A study of Homo sapiens with 6 samples.

How the data were processed

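RNA from normal human epidermal keratinocytes was sequenced in 6 libraries, 1 for each combination of siRNA (control, HDAC8, HDAC9) and stimulation (none, poly(I:C)). The authors deposited 5 tables of 21333 human RefSeq transcripts, each comparing 1 library with unstimulated siControl. The signal values, called LSMean per the file headers, are the authors' scaled read counts per transcript: low values of genes with a single transcript tend to fall on multiples of 1 step per library, with reads shared between transcripts split. Within 0.1 read, 66.3% to 70.5% of such low values were whole in the 6 libraries, against 32.4% to 35.1% of the low values of all transcripts. The step was fitted on the same single-transcript values. The reads behind a value are therefore estimates, and less certain for genes with several transcripts. The total to which the authors scaled each library is not stated, and the smallest deposited signal is 0.0001. The p-value and its step-up FDR are the authors' deposited test of 1 library against 1 library, whose model is not stated. The ratio is the authors' deposited quotient of both signals, and the signed fold change, kept here as a score, is the deposited ratio or minus its inverse. In 2 cells the signed fold change and the ratio disagreed. TopHat2 2.0.8, Partek and the build mm10 are named per the submitters' processing notes. That build is of another species than the human transcripts, so no coordinates are given.

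The siControl column was identical in all 5 tables (largest difference 0), and the deposited totals equalled the sum of the 6 libraries within 0.6%. The lowest geometric mean of a transcript over the 6 libraries was 0.999937, so the tables appear to hold only transcripts at or above 1 by that mean. Such a filter would remove genes at low values over the libraries as a whole, while 6 transcripts at the smallest signal in some library were kept, and HDAC8, IL6, IFNB1 and CCL5 were not analysed here. Symbols that a spreadsheet had turned into dates were restored from the accession for 59 of 59 transcripts. Transcripts were summed to 11720 genes.

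For each comparison, the log2 ratio of value + 1 was taken for genes at 1 or more in at least 1 of the libraries compared, and a change was called at 2-fold. With 1 library per group this is a rule of size, with no p-value. The 8 comparisons were poly(I:C) against none for each siRNA, each silenced library against siControl without and with poly(I:C), and siHDAC9 against siHDAC8 with poly(I:C). The difference in response was the response of the silenced cells minus that of siControl. This difference is signed, so a gene that fell more in the silenced cells counts as having a smaller response. Genes were tested in numbers from 11590 to 11691 per comparison.

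Reads per library were estimated from the value of 1 read, which was 0.116 in siControl, 0.223 in siHDAC8, 0.200 in siHDAC9 and 0.121, 0.150 and 0.175 in the same order with poly(I:C). Ratios have 95% Clopper-Pearson intervals of the conditional binomial share of the estimated reads. Where a library had no read, the fold is given against a floor of 3 reads, which was 0.348, 0.670, 0.601, 0.364, 0.449 and 0.526 in the order above. This fold is not a limit of the 95% interval, whose lower limit lies below it. Ribosomal RNA made up 1.08%, 0.437%, 1.27%, 1.54%, 1.45% and 1.24% of the values, and the 10 highest genes 12.1%, 10.1%, 12.4%, 12.1%, 9.49% and 11.3%. Counts of changed genes are given beside their mean in 100 simulated pairs of libraries that differ by Poisson counting error alone.

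The named genes, 26 gene lists, the 2-fold rule and the main alternatives were chosen before the data were examined. Named genes are HDAC9, MAP2K3, TNF, CXCL8 and CXCL10, the 8 genes with the largest increase and the 8 with the largest decrease per comparison among those at 5 or more in at least 1 library, and the 4 members of each list with the largest absolute ratio. Of the genes this rule names, 1 is not reported here. Only 34 of 42 listed interferon-stimulated genes, 13 of 28 inflammatory cytokines and 11 of 23 chemokines were among the genes analysed here. Counts and medians of a list describe its measured members only, and members at low values over the libraries may be missing. Each list median was ranked among 10000 random lists of the same size, matched on expression in 20 bins, and this percentile describes these libraries only. Setting genes without reads to the floor moved 2 of 210 list medians, by at most 0.0670. Correlations of log2 ratios are across genes. Where comparisons share a control library, the same correlation and covariance were simulated with unchanged libraries.

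The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5, rescaling by the median ratio, and calls at 1.5-fold and 4-fold. A further one was the authors' deposited fold of each gene's most abundant transcript. Use of unstimulated in place of stimulated siControl was added after seeing the data. On simulated libraries, genes planted at 3-fold were recovered in 93%, 93%, 90%, 86%, 91%, 88%, 92% and 86% of cases, in the order of comparisons above, and at 8-fold in 95%, 98%, 98%, 98%, 96%, 98%, 98% and 96%. Of unchanged genes, 99.7% to 99.9% were left uncalled. Coverage of the intervals was checked on 297 to 300 unchanged genes with 5 or more reads per comparison. The true ratio was covered in 95.3%, 95.3%, 95.3%, 98.3%, 95.7%, 96.0%, 94.0% and 94.9% of these genes. Coverage at planted changes was not checked. A planted list reached percentile 100 in each comparison, and 37 to 39 of 40 random lists fell within the central 95%. These simulations hold counting error and no spread between cultures. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.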

Results

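Normal human epidermal keratinocytes, the primary cells that build the outer layer of the skin, were treated with a control siRNA or with an siRNA against HDAC8 or HDAC9. Both targets are histone deacetylases, enzymes that remove acetyl groups from histones and other proteins. After 16 hours of siRNA treatment and 48 to 72 hours of recovery, cells of each kind were profiled by RNA sequencing without stimulation or 24 hours after poly(I:C), a synthetic double-stranded RNA that mimics viral RNA. The design asks how silencing of either enzyme changes the keratinocyte transcriptome at rest and during this response. The 6 libraries are called siControl, siHDAC8 and siHDAC9, each without and with poly(I:C), and each group holds 1 library. The labels give the same range of 48 to 72 hours of recovery for every library. The recovery time of each library is thus not known and may differ between them. There are no replicates within a group, so no difference between 2 libraries was tested. A fit of an effect of poly(I:C) common to the siRNAs was not run. The words "rose" and "fell" below mean a difference of 2-fold or more between 2 libraries on the log2(value + 1) scale. Gene levels are the deposited scaled read counts, summed over the transcripts of each of 11720 genes. The estimated depth was 5050055 reads in siControl, 2408416 in siHDAC8, 2687555 in siHDAC9, and 4762189, 3710443 and 3127799 in the same order with poly(I:C). Intervals below are 95% counting intervals from these estimated reads and cover counting error only.

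HDAC9 was at 10.9 in siControl and 8.65 in siHDAC8, against 0.342 in siHDAC9. With poly(I:C), HDAC9 levels were 18.6, 26.5 and 0.934 in the same order. HDAC9 was thus 32.0-fold lower in siHDAC9 than in siControl without stimulation (interval 7.32 to 228, about 2 reads in siHDAC9) and 19.9-fold lower with it (8.89 to 66.2). HDAC8 was not analysed here, so its silencing was not checked. MAP2K3, the kinase that activates p38 MAP kinases, was the member of its pathway list that rose most in unstimulated siHDAC8. MAP2K3 rose from 9.62 in siControl to 40.5 in siHDAC8 (4.21-fold, 3.23 to 5.52) and 37.1 in siHDAC9 (3.86-fold, 2.96 to 5.06). With poly(I:C), MAP2K3 was at 19.0 in siControl, 61.5 in siHDAC8 (3.25-fold higher, 2.70 to 3.93) and 58.3 in siHDAC9 (3.08-fold higher, 2.54 to 3.75).

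**Figure D1:**
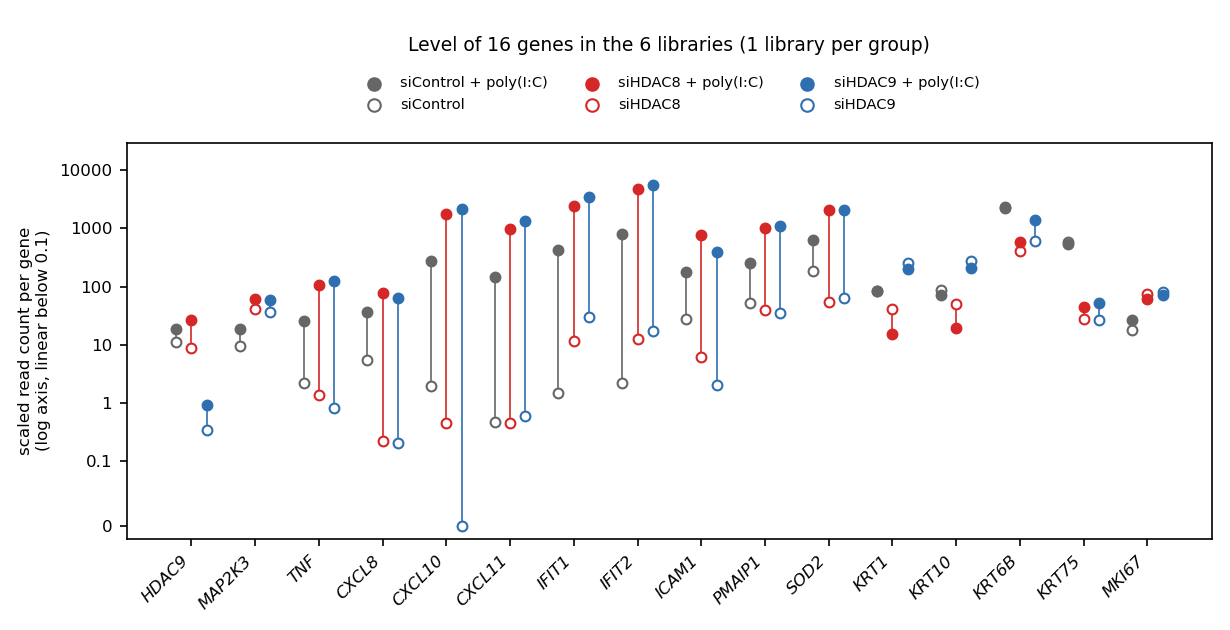
Scaled read count per gene (log axis, linear below 0.1) of 16 genes in the 6 libraries, with open points for unstimulated and filled points for poly(I:C) libraries and 1 colour per siRNA. MAP2K3 lies higher in all silenced libraries than in its siControl counterpart, and CXCL10 reached 280 in siControl, 1750 in siHDAC8 and 2120 in siHDAC9 with poly(I:C).

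In unstimulated siHDAC8, genes of the activated and differentiating keratinocyte were lower and genes of the cell cycle higher than in siControl. Of the activated keratinocyte and antimicrobial list, 12 of 14 measured members fell (median log2 ratio -1.72), among them PI3, the protease inhibitor elafin, from 76.0 to 9.16, KRT6B from 2280 to 416 and S100A8 from 109 to 24.1. Of the epidermal differentiation list, 12 of 32 members fell and 1 rose (median -0.79), with SPRR2E falling from 83.9 to 6.93, SPRR2A from 32.8 to 2.68 and the desmosomal cadherin DSG1 from 256 to 53.6. Cell cycle and proliferation genes rose in 19 of 32 cases and fell in 0 (median 1.11), with the proliferation marker MKI67 rising from 17.9 to 73.5 and TK1 from 8.46 to 30. In all, 585 genes rose and 592 fell in siHDAC8, where counting error alone gave means of 7.72 and 17.6 genes in 100 simulated pairs of unchanged libraries.

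Inflammatory mediators were lower in unstimulated siHDAC8, whereas some interferon-stimulated genes were higher. Among cytokines, 10 of 13 measured members fell (median -1.19), including the alarmin IL33 from 28.2 to 2.86, IL1B from 15.8 to 2.46 and IL32 from 54.5 to 14.7. Of 9 chemokines, 6 fell (median -1.38), among them CXCL14 from 1210 to 337 and CXCL8, which had about 1 read in siHDAC8 and was 24.3-fold lower (4.17 to 983). NF-kB pathway genes fell in 4 of 23 cases (median -0.36), including the adhesion molecule ICAM1 from 27.6 to 6.04 and SOD2 from 189 to 53.5. Interferon-stimulated genes rose in 7 of 30 cases and fell in 2 (median 0.42), with IFIT1 rising 7.57-fold (4.06 to 15.2), IFI6 6.15-fold (3.45 to 11.5) and IFIT2 5.59-fold (3.26 to 9.96). MHC class I genes rose in 4 of 17 cases (median 0.35), whereas 0 of 20 nucleic acid sensing genes passed 2-fold in either direction (median -0.30).

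The unfolded protein and amino acid stress list rose in 9 of 20 cases in unstimulated siHDAC8 (median 0.59), among them the chaperones HSP90B1 from 115 to 355 and CALR from 256 to 714, and SDF2L1 from 10.2 to 34.6. Of 22 cholesterol synthesis genes 3 rose (median 0.52), including the sterol isomerase EBP from 28.9 to 62.6 and the sterol reductase DHCR7 from 68.7 to 139.5. The TGF-beta response and matrix list fell in 6 of 19 cases (median -0.54), with the collagenase MMP1 falling from 29.5 to 4.91. Of 18 basal keratinocyte genes 1 rose, KRT15 from 37.0 to 119, and 1 fell, the laminin chain LAMB3 from 1337 to 589. The largest decreases outside these lists included SPRR2G from 108 to 2.91, the methyltransferase NNMT from 50.5 to 1.12, the hair-follicle keratin KRT75 from 574 to 28.2, PRR9 from 160 to 14.5 and MAP1B from 247 to 23.2. The largest increases included IGFBP5 from 4.29 to 37.3, the oxytocin receptor OXTR from 1.39 to 15.9, KRT7 from 36.6 to 228 and NLRP2, 14.6-fold higher (7.44 to 31.4). Members of the SPRR2 and KRT6 families have near-identical sequences, so reads could be split between them and their single values are uncertain.

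In unstimulated siHDAC9, cell cycle and interferon-stimulated genes were higher and cytokines and chemokines lower than in siControl. In all, 604 genes were higher and 660 lower (5.56 and 11.9 by counting error alone). Cell cycle genes rose in 25 of 32 cases (median 1.36), including PLK1 from 5.33 to 30.3 and MKI67 from 17.9 to 81.8. Interferon-stimulated genes rose in 12 of 33 cases and fell in 1 (median 0.58). IFIT1 was 19.7-fold higher (11.2 to 37.9), MX1 20.6-fold (8.86 to 69.4) and IFI6 13.6-fold (8.07 to 24.6). Cytokines fell in 6 of 13 cases (median -0.83), with IL32 falling from 54.5 to 6.56 and IL1A from 189 to 52.3. Of 9 chemokines, 6 fell and 1 rose (median -1.64), with CXCL14 falling from 1210 to 350 and CXCL1, at about 3 reads, 36.1-fold lower (12.1 to 176). NF-kB pathway genes fell in 6 of 23 cases (median -0.21), with ICAM1 falling from 27.6 to 2 and TNFAIP3, the NF-kB inhibitor A20, from 124 to 38.1.

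Of 32 epidermal differentiation genes, 13 fell and 3 rose in unstimulated siHDAC9 (median -0.23). LCE3E fell from 28.7 to 1 and LCE3D from 62.5 to 5.81, whereas the suprabasal keratins KRT1 (85.5 to 250) and KRT10 (88.6 to 274) rose. KRT1 and KRT10 are named for this comparison after their values were seen. Activated keratinocyte genes fell in 6 of 14 cases (median -0.82), including PI3 from 76.0 to 5.21 and the antimicrobial RNASE7 from 82.5 to 10.6. The TGF-beta response and matrix list fell in 9 of 19 cases (median -0.94), including VIM from 306 to 33.4 and TGFB2 from 49.7 to 7.56. MMP1 went from 29.5, which is 49.1-fold the floor of 3 reads, to no read. The early response genes FOS (5.10 to 31.1) and EGR1 (37.1 to 161) rose, while the MAP kinase list as a whole had a median of -0.10 in both silenced libraries, with 5 rising and 2 falling of 28 in siHDAC9. Of 20 unfolded protein genes 5 fell and 0 rose (median -0.14), and of 22 cholesterol synthesis genes 3 rose and 0 fell (median 0.06). Basal keratinocyte genes fell in 3 of 18 cases and rose in 1 (median -0.10), with the laminin chains LAMB3 (1337 to 366) and LAMA3 (504 to 230) falling. MHC class I and nucleic acid sensing genes had medians of 0.03 and -0.19.

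Of 11709 genes, 297 rose in both siHDAC8 and siHDAC9, against 30.2 for independent lists, and 266 fell in both, against 33.4. Simulated unchanged libraries with the same shared control gave 0.63 and 0.64 genes. Across genes, which are not independent replicates, the log2 ratios correlated with Pearson r = 0.643 (Spearman 0.607), against 0.349 simulated, and the covariance was 0.269, against 0.0188 simulated. Part of the excess may come from the shared siControl library, which could not be split. Between siHDAC8 without and siHDAC9 with poly(I:C), which share no library, r was 0.304, and between siHDAC9 without and siHDAC8 with poly(I:C) it was 0.329. Deviations that both siControl libraries have in common would raise these values too.

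Poly(I:C) raised 196 genes and lowered 84 in siControl (2.43 and 2.83 by counting error alone). Interferon-stimulated genes rose in 27 of 34 cases and fell in 0 (median 2.28). IFIT2 rose from 2.20 to 799, IFIT1 from 1.51 to 426 and IFIT3 from 5.67 to 653. OASL, with no read in siControl, reached 36.9, which is 106-fold the floor of 3 reads. Of 11 chemokines 5 rose (median 0.78), including CXCL10 from 1.97 to 280, CXCL11 from 0.464 to 147 and CCL20 from 0.846 to 23.3. CX3CL1 was 101-fold higher (63.3 to 175). Cytokines rose in 6 of 13 cases (median 0.72), with TNF rising from 2.20 to 25.5, IL36G from 3.78 to 35.5 and LIF from 10.9 to 50.7, and CXCL8 rose from 5.45 to 36.4. NF-kB genes rose in 10 of 23 cases (median 0.56), including TNFAIP2 from 13.9 to 229, BIRC3 from 2.78 to 42.6 and ICAM1 from 27.6 to 181.

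Of 21 nucleic acid sensing genes 1 rose in siControl, the transcription factor IRF1, from 4.29 to 68.4. Of 16 MHC class I genes 2 rose (median 0.39), with TAP1 rising from 34.2 to 74.3. HLA-F went from no read to 2.83, which is 8.14-fold the floor of 3 reads. Of 28 MAP kinase pathway genes 2 rose, ATF3 from 24.9 to 105 and EGR1 from 37.1 to 87.6. None of 32 epidermal differentiation, 18 basal keratinocyte, 14 activated keratinocyte, 32 cell cycle and 22 cholesterol synthesis genes passed 2-fold. In the other lists, the urokinase receptor PLAUR rose from 10.4 to 92.3 and the stress factor DDIT3 fell from 7.79 to 1.45. The largest decreases included CIB1 from 6.32 to 0.582 and the non-coding RN7SL1 from 25.8 to 5.83. With a pseudocount of 5, which weighs down genes at low levels, 95 genes were higher and 5 lower. Whether this library also holds reads or RNA of the stimulated silenced libraries was left open, and such reads would make the response of the control cells look larger than it was.

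**Figure D2:**
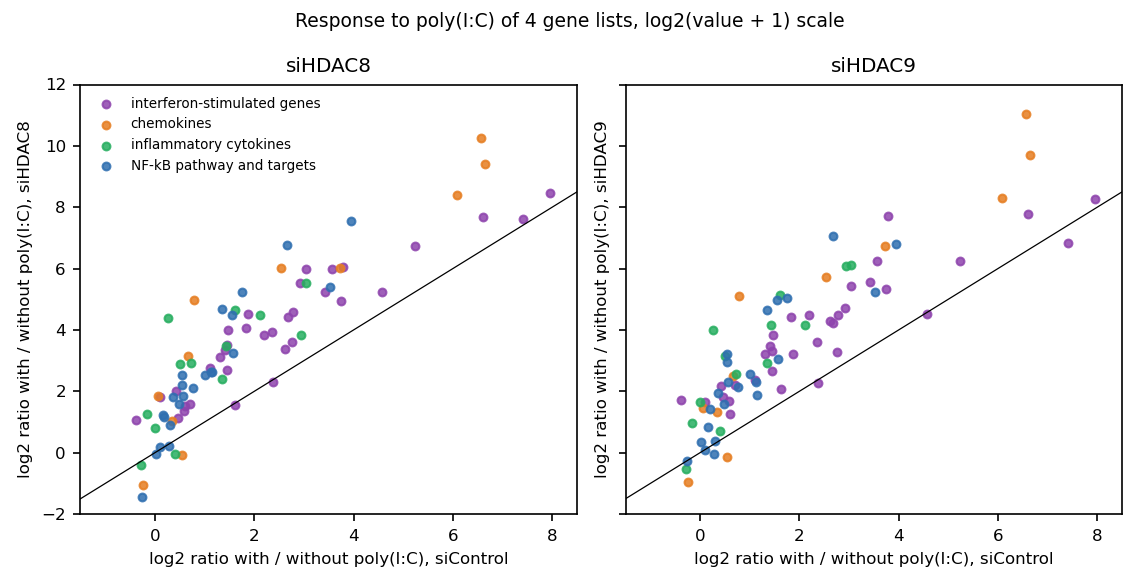
The log2 ratio with over without poly(I:C) in siControl (horizontal) and in siHDAC8 or siHDAC9 (vertical) for the measured genes of 4 lists, with a line where both ratios are equal. Most points lie above the line, with a median difference of 1.59 for interferon-stimulated genes in siHDAC8 and 1.55 in siHDAC9.

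In siHDAC8 cells, poly(I:C) raised 639 genes and lowered 897 (24.2 and 14.3 by counting error alone). All 34 measured interferon-stimulated genes, of 42 listed, rose (median 3.89), including IFIT2 from 12.3 to 4720 and IFIT1 from 11.4 to 2419. Of 11 chemokines 9 rose and 1 fell (median 4.98), with CXCL10 and CXCL11, each at about 2 reads without stimulation, reaching 1750 (3915-fold, 1084 to 32347) and 993 (2221-fold, 615 to 18356). Cytokines rose in 10 of 13 cases (median 2.93), including TNF from 1.34 to 108 and LIF from 4.47 to 122. TSLP went from no read to 24.4, which is 36.4-fold the floor of 3 reads. NF-kB genes rose in 18 of 23 cases and fell in 1 (median 2.20), with TNFAIP2 rising from 3.80 to 899, ICAM1 from 6.04 to 775 and SOD2 from 53.5 to 2038. IRF1 rose from 2.91 to 365, with 9 of 21 sensing genes higher, and MHC class I genes rose in 7 of 17 cases (median 0.87), including HLA-B from 44.3 to 229 and B2M from 321 to 1080.

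Epidermal differentiation genes fell with poly(I:C) in 12 of 30 cases in siHDAC8 and rose in 0 (median -0.77, against -0.21 for all genes). KLK6 fell from 10.9 to 1.90, CALML5 from 55.9 to 14.5 and the cornified envelope protein LCE3D from 17.4 to 4.34. Cholesterol synthesis genes had a median of -0.57 with 1 of 22 passing 2-fold, cell cycle genes -0.45 with 2 of 32 and unfolded protein genes -0.40, with PPP1R15A rising from 61.9 to 584 and DDIT4 falling from 411 to 107. The largest decreases included ID3, an inhibitor of helix-loop-helix factors, from 41.8 to 0.749, the Wnt antagonist DKK1 from 84.9 to 7.04, the Wnt receptor FZD2 from 26.4 to 2.10 and MAF from 47.8 to 5.09. With the libraries rescaled by their median ratio, 804 genes rose and 597 fell, so that the lower share went from 58.4% to 42.6%.

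In siHDAC9 cells, poly(I:C) raised 682 genes and lowered 1309 (21.5 and 18.9 by counting error alone). All 34 measured interferon-stimulated genes again rose (median 3.73), with IFIT2 rising from 17.2 to 5640. RSAD2, the antiviral protein viperin, went from no read to 208, which is 346-fold the floor of 3 reads. Of 11 chemokines 9 rose (median 5.09). CXCL10 went from no read to 2120, which is 3526-fold the floor of 3 reads. CXCL11, at about 3 reads without stimulation, reached 1322 (2200-fold, 752 to 10664). Cytokines rose in 10 of 13 cases (median 3.14), including TNF from 0.802 to 124, IL36G from 0.793 to 121 and CSF1 from 5.41 to 115. NF-kB genes rose in 17 of 23 cases (median 2.30), with ICAM1 rising from 2 to 396, and PLAUR rose from 2.20 to 447. MHC class I genes rose in 10 of 17 cases (median 1.06), including HLA-B from 40.9 to 270 and their transactivator NLRC5 from 3 to 33.8, and 8 of 21 sensing genes rose, with IRF1 going from 5.01 to 239.

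Epidermal differentiation genes had a median of about 0 with poly(I:C) in siHDAC9, with 2 rising and 2 falling of 32, including TGM1 from 14.4 to 47.0 and GRHL3 from 24.1 to 8.70. Of 14 activated keratinocyte genes 3 rose (median 0.20), including PI3 from 5.21 to 53.3 and KRT6B from 610 to 1390. Cell cycle genes had a median of -0.68, against -0.31 for all genes, with 5 of 32 falling, among them PLK1 from 30.3 to 13.9. DKK1 fell from 89.6 to 4.38, VAV3 from 37.3 to 1.40, MAF from 73.4 to 4.38 and MYCL from 28.9 to 1.75. Rescaled by the median ratio, 920 genes rose and 805 fell, so that the lower share went from 65.7% to 46.7%.

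The responses of the silenced cultures resembled each other although they share no library. Across 11717 genes their log2 ratios had r = 0.789, 465 genes rose in both against 37.2 for independent lists, and 460 fell in both against 100. With siControl, r was 0.559 for siHDAC8 and 0.562 for siHDAC9. Of the 196 genes that rose in siControl, 135 also rose in siHDAC8 and 139 in siHDAC9, against 10.7 and 11.4 for independent lists. Of the 84 that fell in siControl, 13 and 22 fell, against 6.43 and 9.38. Reads or RNA of the stimulated silenced libraries in siControl with poly(I:C), a question left open, would raise these correlations and overlaps with siControl.

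The measured response of inflammatory and interferon-stimulated genes was larger in the silenced libraries than in siControl. The median difference in response from siControl was 1.59 for the 34 interferon-stimulated genes in siHDAC8 and 1.55 in siHDAC9, with 23 and 27 of them differing by 2-fold or more. It was 2.31 and 2.23 for 11 chemokines, 2.05 and 2.03 for 13 cytokines, and 1.47 and 1.48 for 23 NF-kB genes. ICAM1 had a difference of 4.11 in siHDAC8 and 4.38 in siHDAC9, CXCL1 of 4.21 and 4.32, and ATF3 of 3.67 and 3.84. That of CXCL10 was 3.68 and 4.49, but it had about 2 reads in unstimulated siHDAC8 and none in siHDAC9, so the size in siHDAC9 is set by the pseudocount. CXCL1 had about 3 reads in unstimulated siHDAC9, and its difference there also moved with the pseudocount. MAP2K3 went the other way by less than 2-fold (-0.32 and -0.27). Of the 196 genes that rose in siControl, 104 and 111 had a 2-fold larger response in siHDAC8 and siHDAC9, and 44 and 48 a 2-fold smaller one. These 196 genes were chosen by the same siControl ratio that is subtracted. Noise in that ratio therefore favours smaller responses among them. Over all genes, 578 responses were 2-fold larger and 768 smaller in siHDAC8, and 619 and 1135 in siHDAC9, where counting error alone gave 74.6 and 60.6, and 69.3 and 65.1. Here smaller means a lower signed log2 ratio, so genes that fell more in the silenced cells than in siControl are included. With poly(I:C), 84 genes fell in siControl, 897 in siHDAC8 and 1309 in siHDAC9. Rescaled by the median ratio, 718 responses were larger and 632 smaller in siHDAC8, and 848 and 822 in siHDAC9, so the excess of smaller signed responses was not kept. All of these differences rest on the single siControl library with poly(I:C), for which the open question of foreign reads or a weaker stimulation applies. For cytokines, chemokines and NF-kB genes they include lower levels before stimulation (median log2 ratios -1.19 and -0.83, -1.38 and -1.64, and -0.36 and -0.21 in unstimulated siHDAC8 and siHDAC9), and the cytokine median in siHDAC8 with poly(I:C) was 0.00 against siControl with poly(I:C).

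**Figure D3:**
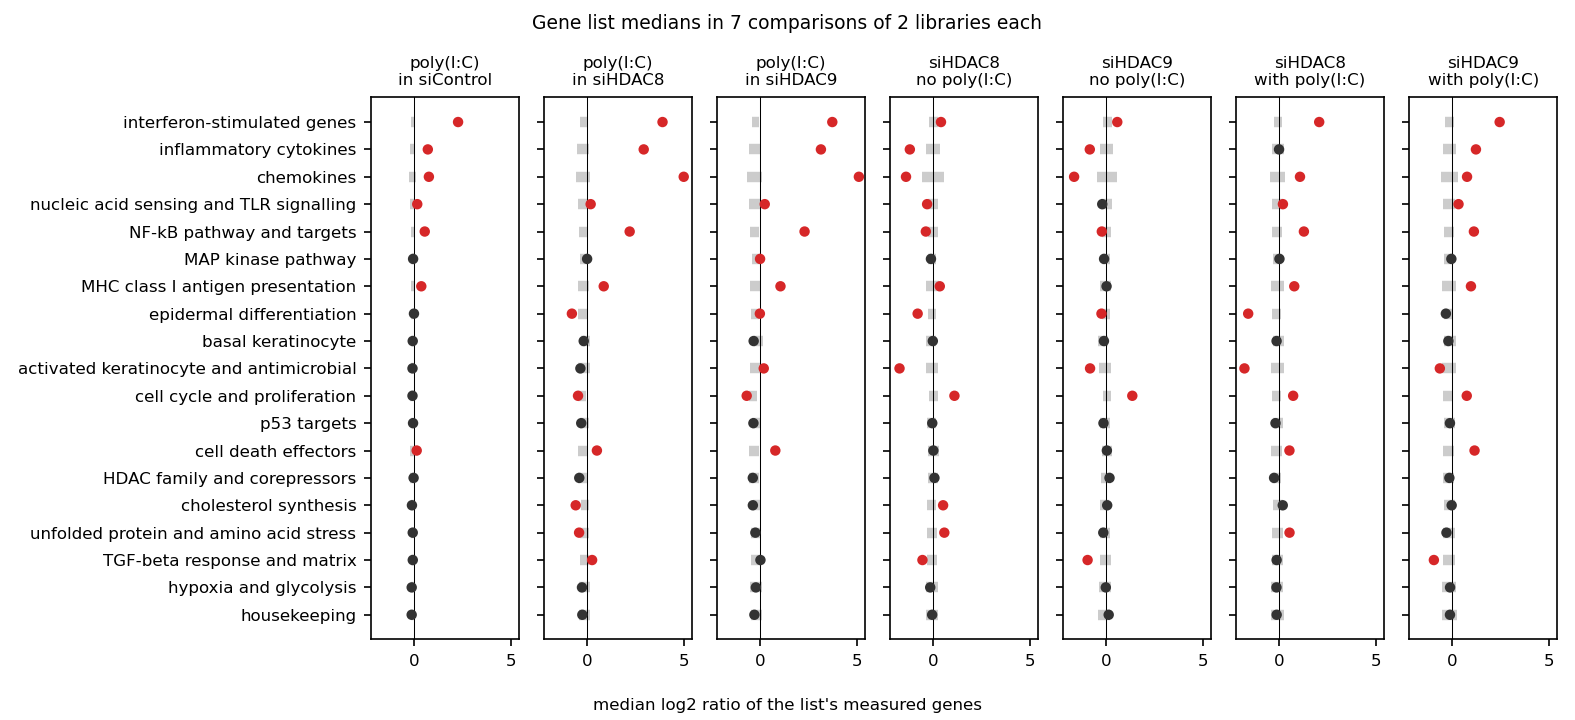
Median log2 ratio of the measured genes of 19 lists in 7 comparisons, with grey bars for the central 95% of 10000 random lists matched on expression and red points for medians at or beyond that range. The interferon-stimulated genes had medians of 2.28, 3.89 and 3.73 for poly(I:C) and of 2.07 and 2.45 for silencing in its presence.

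With poly(I:C) present, interferon-stimulated genes were higher in both silenced libraries than in siControl. Ratios against siControl with poly(I:C) rest on this single library, so the open question of foreign reads or a weaker stimulation applies to them too. In siHDAC8, 30 of 34 rose (median 2.07), including IFIT2 from 799 to 4720, RSAD2 from 15.9 to 109 and the RNA sensor DDX58 from 101 to 557. In siHDAC9, 33 of 34 rose (median 2.45), including RSAD2 to 208, MX1 from 37.5 to 313 and IFI6 from 13.8 to 125. CXCL10 was 6.25-fold higher in siHDAC8 (5.98 to 6.54) and 7.57-fold in siHDAC9 (7.24 to 7.92), and TNF 4.24-fold (3.63 to 4.96) and 4.86-fold (4.17 to 5.70). CXCL8 rose 2.15-fold in siHDAC8 (1.86 to 2.48) and was 1.73-fold higher in siHDAC9 (1.48 to 2.02). NF-kB genes rose in 15 and 14 of 23 cases and fell in 1 and 0 (medians 1.28 and 1.13), and MHC class I genes in 8 and 7 of 17 (medians 0.79 and 0.97), with HLA-B going from 62.1 to 229 and 270. Cytokines rose in 5 and 8 of 13 cases and fell in 2 and 1 (medians 0.00 and 1.23), and chemokines rose in 7 and 4 of 11 and fell in 1 and 1 (medians 1.08 and 0.77), with CXCL14 falling from 1030 to 163 and 179. TLR3, the endosomal receptor for double-stranded RNA, rose from 2.91 to 12.7 in siHDAC8 and 25.2 in siHDAC9, with 5 of 21 sensing genes higher in each, and 2 and 1 lower.

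Epidermal differentiation genes fell in 23 of 32 cases in siHDAC8 with poly(I:C) (median -1.58), including SPRR2E from 84.6 to 3.60, LCE3D from 51.5 to 4.34 and DSG1 from 252 to 41.0, and activated keratinocyte genes in 12 of 14 (median -1.78), including S100A8 from 105 to 12.9. In siHDAC9, 12 fell and 3 rose of 32 differentiation genes (median -0.32), and 2 of 14 activated keratinocyte genes fell (median -0.63). Cell cycle genes rose in 10 and 8 of 32 cases (medians 0.73 and 0.76), with TOP2A going from 7.41 to 22.2 and 20.3. The TGF-beta response and matrix list fell in 9 of 19 cases and rose in 1 in siHDAC9 (median -0.93), including VIM from 234 to 14.6 and TGFB2 from 45.7 to 2.98, whereas in siHDAC8 3 rose and 3 fell of 19 (median -0.12). SPRR2G fell from 86.8 to 1.35 and 1.23, and the neurofilament NEFL from 323 to 25.3 and 18.2.

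In all, 589 genes rose and 827 fell in siHDAC8 with poly(I:C), and 612 and 1274 in siHDAC9 (4.60 and 6.76, and 5.81 and 10.8, by counting error alone). The medians of all genes were -0.12 and -0.19, and rescaling gave 711 and 688, and 817 and 958, moving the lower share in siHDAC9 from 67.6% to 54.0%. Against siControl without poly(I:C), a choice made after seeing the data, 717 rose and 1166 fell in siHDAC8, and 729 and 1627 in siHDAC9. Against siControl with poly(I:C), 359 rose and 475 fell in both, against 30.8 and 90.1 for independent lists and 0.62 and 0.31 in simulated unchanged libraries. The correlation was 0.714 against 0.427 simulated and the covariance 0.362 against 0.0203, and part of the excess may come from the shared control library.

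Compared directly with poly(I:C) present, siHDAC9 had 327 genes higher and 526 lower than siHDAC8 (12.2 and 14 by counting error alone), and 377 higher and 462 lower when rescaled by the median ratio. Epidermal differentiation genes were higher in siHDAC9, with 15 of 32 rising and 0 falling (median 0.93), led by KRT1 from 15.4 to 202 (13.1-fold, 10.7 to 16.2) and KRT10 from 19.5 to 211 (10.8-fold, 9.03 to 13.1). Activated keratinocyte genes rose in 10 of 14 cases (median 1.19), including S100A8 from 12.9 to 65.7 and PI3 from 12.1 to 53.3. Of 13 cytokines 5 rose, among them IL33 (5.73 to 37.9) and IL36G (29.3 to 121), and 1 fell, IL32, from 36.5 to 13.6 (median 0.61). The TGF-beta response and matrix list fell in 9 of 18 cases (median -0.83), with VIM falling from 119 to 14.6, and INHBA, a subunit of activin, fell from 547 to 68.4 and TGM2 from 61.9 to 8.6. Unfolded protein and amino acid stress genes fell in 5 of 20 cases (median -0.58), including PSAT1 from 68.6 to 24.2. Of 34 interferon-stimulated genes, 1 passed 2-fold but 32 lay above 0 (median 0.42, percentile 100 among random lists). MAP2K3 was at 61.5 and 58.3. This comparison does not use either control library.

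The authors' deposited tables compared each library with unstimulated siControl at the level of transcripts. In the authors' deposited table, 700 of 21333 transcripts had an adjusted p under 0.05 for siHDAC8 and 781 for siHDAC9. In the authors' deposited tables for poly(I:C), the numbers were 83 for siControl, 1315 for siHDAC8 and 1717 for siHDAC9. A high level did not always go with a small p where siControl was at the smallest value: OASL, at 176 in siHDAC8 with poly(I:C), had p = 0.886 in the authors' deposited table.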

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

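All differences in this part were picked out after the data were seen, as genes passing 2-fold in opposite directions or list medians of opposite sign, and the search was widened to all named genes once KRT1 and KRT10 had been noticed. None of them was tested.

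Some genes differed from siControl in opposite directions in siHDAC8 and siHDAC9. Without poly(I:C), the suprabasal keratin KRT1 had log2 ratios of -1.05 in siHDAC8 and 1.54 in siHDAC9, a difference of 2.59. PODXL, which encodes podocalyxin, had 1.37 and -1.08 (difference -2.46), and the transglutaminase TGM2 had 1.37 and -1.08 (difference -2.45). With poly(I:C), KRT1 had -2.35 and 1.28 (difference 3.63), its partner KRT10 -1.83 and 1.54 (difference 3.37), PLA2G4F -1.19 and 1.53 (difference 2.73) and FAM111B -1.04 and 1.65 (difference 2.69). In the other direction, TMEM204 had 1.17 and -2.43 (difference -3.60), INHBA 1.16 and -1.82 (difference -2.98), TGM2 1.21 and -1.51 (difference -2.71) and the gelatinase MMP9 1.01 and -1.26 (difference -2.27).

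The response to poly(I:C) went in opposite directions for a few genes. Between siControl and siHDAC8, SLC29A3 had 1.74 and -1.80 (difference -3.54), CHD1L 1.64 and -1.54 (difference -3.18) and the ribosomal RNA gene RNA5-8S5 -2.21 and 1.01 (difference 3.23). The ribosomal RNA share of the values also differed between libraries. It was 0.437% in siHDAC8 and 1.45% with poly(I:C), and 1.08% and 1.54% in siControl, so the RNA5-8S5 ratios may not be a response of the cells. Between siControl and siHDAC9, MECR had -2.31 and 2.26 (difference 4.58), DHPS 1.91 and -2 (difference -3.90) and NUSAP1 1.36 and -1.19 (difference -2.55). Between siHDAC8 and siHDAC9, the readthrough symbol ARMCX5-GPRASP2 had -2.75 and 1.66 (difference 4.41) and PANK1 1.08 and -1.77 (difference -2.85). The median response of the epidermal differentiation list was -0.77 in siHDAC8 and about 0 in siHDAC9, a difference of 0.769, and the sign in siHDAC9 turned with a pseudocount of 0.1.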

How the results depend on the processing

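List medians near 0 changed sign in 29 cases with rescaling by the median ratio, 7 with values of at least 5, 5 with the authors' deposited fold, 3 with a pseudocount of 0.1 and 2 with a pseudocount of 5, and none of these had a main value beyond 0.232 in size. They are medians of the MAP kinase, epidermal differentiation, basal keratinocyte, cell cycle, p53, HDAC family, cholesterol, unfolded protein, TGF-beta, hypoxia, housekeeping, fibroblast and histone lists. Among them, the median response of the epidermal differentiation list in siHDAC9 went from 2.16e-05 to -0.00176 with a pseudocount of 0.1. Of the named log2 ratios 1 changed sign, the difference in response of HDAC9 in siHDAC9, from -0.19 to 0.47 with a pseudocount of 0.1. Of the counts of genes, 70 moved by more than 1.5 times and 80 did not. Of the list medians, 44 moved out of the 95% interval from resampling the list members and 1059 did not. A named log2 ratio counted as moved outside its counting interval, widened to include the main value, and a difference in response when it changed by more than 1. Of the named log2 ratios 196 moved, 154 of them with a pseudocount of 5, and 470 did not. In each group of values below, genes higher are given before genes lower. With no minimum, no count of genes changed, and no list median or correlation was counted as moved. Some correlations changed slightly, such as that between HDAC8 and HDAC9 silencing without poly(I:C), from 0.643039 to 0.643016. This setting says nothing about stability. Where a value moved for a lower or higher fold, the construction of the setting is the cause. The same holds for counts between 2 libraries with other pseudocounts. A pseudocount of 5 makes every ratio smaller and one of 0.1 makes it larger. A filter at 5 only removes genes from a count. For the other moves the cause was not tested.

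With calls at 1.5-fold, the poly(I:C) counts were 463 and 407 in siControl, 1204 and 2647 in siHDAC8, and 1131 and 3447 in siHDAC9. Silencing without poly(I:C) gave 1604 and 1581 for HDAC8 and 1678 and 1629 for HDAC9, and with it 1337 and 2246, and 1309 and 2930. The direct comparison of siHDAC9 with siHDAC8 gave 978 and 1633, and larger and smaller responses were 1291 and 2237 in siHDAC8 and 1201 and 2857 in siHDAC9.

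With calls at 4-fold, the counts in the same order were 56 and 8, 210 and 71, 266 and 122, then 40 and 91, 52 and 117, 63 and 106, 109 and 196, then 29 and 47, and 110 and 73, and 134 and 126.

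With a pseudocount of 5, poly(I:C) gave 95 and 5 in siControl, 436 and 270 in siHDAC8, and 505 and 469 in siHDAC9. The lower share was then 38.2% in siHDAC8 and 48.2% in siHDAC9, so the excess of lower genes was not kept. Silencing gave 200 and 274 for HDAC8 and 191 and 353 for HDAC9 without poly(I:C), and 324 and 346, and 378 and 597 with it. The direct comparison gave 101 and 171. Responses were larger for 332 and smaller for 197 genes in siHDAC8, and larger for 414 and smaller for 367 in siHDAC9. The correlations between HDAC8 and HDAC9 silencing were 0.669 without and 0.754 with poly(I:C), and that between their responses 0.862.

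With a pseudocount of 0.1, 185 genes were lower with poly(I:C) in siControl, the direct comparison gave 515 and 799, and 1158 responses were smaller in siHDAC8. The same correlations were 0.621, 0.675 and 0.711. With values of at least 5, 37 genes were lower in siControl with poly(I:C), and the correlations were 0.661, 0.743 and 0.833. The authors' deposited fold was taken for the most abundant transcript of each gene, with no pseudocount, and not for the sum over transcripts. By it, poly(I:C) in siControl gave 429 and 394, silencing of HDAC8 1042 and 1018, and of HDAC9 1091 and 1071. Rescaled by the median ratio, 597 genes were lower with poly(I:C) in siHDAC8 and 805 in siHDAC9.

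Depth limits genes at low levels most, since 1 read is worth 0.116 in siControl and 0.223 in siHDAC8. A paired fit of poly(I:C), with the 3 siRNAs as pairs, was not run.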

Other observations

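The tests that weigh explanations for the 2 patterns at the end of this part, and their bounds, were chosen only after the results were seen, whereas the gene lists were fixed earlier.

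Cell death and p53 target genes held a few strong responders to poly(I:C). APOL1, an apolipoprotein that kills trypanosomes, rose from 1.36 to 19.0 in siControl, 2.41 to 91.3 in siHDAC8 and 1.57 to 136 in siHDAC9, and the cell death effectors rose in 3, 7 and 9 of 20 cases and fell in 0, 0 and 1 (medians 0.15, 0.52 and 0.80). Against siControl with poly(I:C), 8 and 11 of them were higher in siHDAC8 and siHDAC9, and without it 1 and 0. The BH3-only genes PMAIP1 (51.6 to 259, 38.9 to 1030 and 34.9 to 1120) and BBC3 (6.49 to 25, 6.04 to 115 and 8.82 to 129) rose with poly(I:C) in all 3 cultures. Of 22 p53 targets 2, 3 and 4 rose, and 0, 5 and 4 fell, including TP53INP1 from 135 to 37.9 in siHDAC8 and 101 to 23.9 in siHDAC9. The sign of the p53 list median turned with rescaling in several comparisons, poly(I:C) in siControl among them, so no direction is given.

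Other deacetylases moved little without poly(I:C), with 0 of 22 members of the HDAC family and corepressor list past 2-fold in siHDAC8 and 1, HDAC9 itself, in siHDAC9. With poly(I:C), 2 rose and 4 fell of 22 in siHDAC8, with HDAC9 itself among those that rose. In siHDAC9, where HDAC9 lay below the minimum of 1 and was not counted, 0 rose and 5 fell of 21. Among those that fell, the mitochondrial deacetylase SIRT3 fell 14.7-fold in siHDAC8 (3.62 to 132) and 23.3-fold in siHDAC9 (5.62 to 186), to about 2 reads in each. Of 15 hypoxia and glycolysis genes, 1 rose and 2 fell with poly(I:C) in each silenced culture, including the growth factor VEGFA from 84.1 to 199 and 44.5 to 212 and the glucose transporter SLC2A1 from 329 to 115 and 512 to 165. Among 15 housekeeping genes 0, 0 and 1 fell with poly(I:C) in siControl, siHDAC8 and siHDAC9, and among 7 replication-dependent histones 0 passed 2-fold with poly(I:C) in any culture. Of the markers of other cell types, COL1A1 of fibroblasts was at 28.4 in siControl, 7.6 in siHDAC8 and 6.21 in siHDAC9, and at 21.4, 4.94 and 2.45 with poly(I:C), and of 4 measured fibroblast markers 2 rose and 1 fell in unstimulated siHDAC8. MITF, the measured melanocyte marker, was at 1.41 and 4.64 in siControl without and with poly(I:C). The leukocyte markers CD68 and CD74 stayed at or below 18.7 and 4.64. No interferon gene, endothelial marker or mitochondrial transcript was analysed here.

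The siControl library with poly(I:C) lay about the same share of the way from unstimulated siControl to the mean of the stimulated silenced libraries for many genes, with a median of 0.150 over 34 interferon-stimulated genes (quartiles 0.134 and 0.190) and 0.184 over 121 raised genes. Rescaling did not remove the larger response of the silenced cultures, since the smaller median difference of the interferon-stimulated genes was still 1.70. This outcome was close to fixed, as the median log2 ratios of all genes were small (-0.31 for poly(I:C) in siHDAC9). The share itself was not recomputed, so whether scaling accounts for it was not tested. A weaker poly(I:C) response of the control cells and reads or RNA of the stimulated silenced libraries in this library both call for the median share of 0.220 found over the 36 lowered genes, so this value gives neither any support over the other, and neither does a mixture fit with weights of 0.827 for siControl, 0.0859 and 0.0870 for siHDAC8 and siHDAC9 with poly(I:C) and 0 for both without it, since it allowed no negative weights. Genes that differed with silencing and not with poly(I:C) did not separate them, with a median share of 0.108 (42 genes chosen against unstimulated siControl) or 0.0874 (36 genes chosen against stimulated siControl), between the values either explanation needs. Among these, the lower genes had medians of 0.117 under both choices, whereas the 11 higher ones were at 0.0565 and -0.0292. Only the second lies under the bound of 0.05 that goes against such reads. The library used for each choice also enters the share. Its noise moves the share up when genes are chosen against unstimulated siControl and down against stimulated siControl. The bound therefore cannot decide here.

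Many genes differed from siControl in the same direction in siHDAC8 and siHDAC9. Counting error does not account for this pattern, since the correlation exceeded the simulated value by 0.294. Noise of the shared siControl library does not account for all of it, since the smaller correlation with no shared library was 0.304, only just past the bound of 0.3 set for it. With a pseudocount of 0.1 that correlation was 0.284, under the bound, though still above the 0.1 that such noise alone was taken to allow. A common effect of the control siRNA, the transfection or the culture may also be at work and was not tested, and the overlap of both silencing programmes remains a hypothesis.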
